A study of Mus musculus with 8 samples.

How the data were processed

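RNA was measured in 8 libraries of cultured mouse lung ILC2s, 2 each of WT control, STAT3-KO control, WT with IL-33 and STAT3-KO with IL-33. Total RNA was isolated with a column kit, per the labels' protocols. The deposited table holds 1 FPKM value per gene and library (fragments per kilobase of gene, scaled to the depth of the library), which the authors made with Bowtie2 and RSEM on the mouse genome GRCm38, per the submitters' processing notes. Those notes give no versions, annotation release, filter or strand setting. The table lists 22075 genes, of which 0 are at 0 in every library, and 14 symbols occur more than once, so that genes were joined by Ensembl identifier. Of these identifiers, 22041 are in GENCODE M21, which gave positions, gene classes and merged exon lengths.

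Each deposited FPKM value times the merged exon length was checked against whole numbers of reads. Among values of at most 100 reads, 93.5% to 94.6% per library lay within 0.02 of a whole multiple of 1 step, and the step gave the depth. It was 16780135 and 15843685 reads for WT control, 16817362 and 16044293 for STAT3-KO control, 19905817 and 16276801 for WT with IL-33, and 16304962 and 17771459 for STAT3-KO with IL-33. RSEM by itself gives estimated rather than whole counts, so the counting behind the values is not fully described by the notes. A count of 3 reads in a gene of 1 kb corresponds to between 0.151 and 0.189 FPKM, which covers counting error alone. Between replicates the variance exceeded counting error 12.6-fold to 29.6-fold (chi-square per degree of freedom), so the spread between libraries, not depth, set the precision of abundant genes. Reads of near-identical genes, overlapping genes and antisense genes cannot be told apart in such a table.

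All tests were made on log2(FPKM + 1), with a pseudocount of 1, for the 11877 genes with an FPKM of at least 1 in at least 2 libraries. Linear models with 1 mean per group were fitted over all 8 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend of the prior variance on expression), with 4 residual and a median of 4.46 prior degrees of freedom. The 5 comparisons were IL-33 against control in WT, IL-33 against control in STAT3-KO, STAT3-KO against WT in control, STAT3-KO against WT with IL-33, and the difference between the IL-33 responses of STAT3-KO and WT (the interaction). P values were adjusted by the Benjamini-Hochberg method over all tested genes within a comparison and called at 0.05, and all tests were two-sided. Tables and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

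Before the data were examined, 33 lists were fixed, 22 of genes and 11 of markers of other cells. The gene lists covered effector cytokines, chemokines, ILC2 identity and receptors, the methionine cycle, serine and folate metabolism, methyltransferases and mitochondrially encoded mRNAs. Others covered the nuclear respiratory chain, the TCA cycle, glycolysis, fatty acids, cholesterol synthesis, STAT3 targets, JAK-STAT components, NF-kB response genes and the cell cycle. The rest covered co-stimulatory and inhibitory receptors and ligands, interferon-stimulated genes, ATF4 targets, the unfolded protein response, cell death, and stress and immediate-early genes. The marker lists covered T cells, NK cells and ILC1, ILC3, B cells, macrophages and monocytes, dendritic cells, mast cells and basophils, granulocytes, epithelial and stromal cells, red blood cells and sex-linked genes. Lists with at least 3 tested members, 24 in all, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. With a correlation estimated per list, 0 lists passed in each of the 5 comparisons, with the lowest adjusted p at 0.0511, 0.13, 0.0917, 0.0832 and 0.139 in the order above. List members were also counted with p values adjusted over the list alone.

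Genes were named by a rule fixed at the same time. It took the genes Stat3, Il5, Il13, Il4, Il9, Il6, Csf2, Areg, Il1rl1 and Gata3 in every comparison. It added the 5 largest rises and 5 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 5 FPKM, leaving out unnamed gene models, ribosomal pseudogenes and microRNAs. With 2 libraries against 2, chance alone separates the groups of a gene in 1 of 3 cases. Last, it added up to 4 called members of smallest p from each list, or 1 or 2 abundant members where a list had none. Of the genes this rule named, 7 are not reported here, and the shares of alternatives leave them out.

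The procedure was tested on simulated data drawn from the means and depths of the real libraries, with 200 genes changed by known amounts, 50 each at 1.5-fold, 2-fold, 4-fold and 8-fold. For IL-33 in WT (11618 genes) it recovered 0%, 26%, 80% and 94% in that order and called 13 of 11398 unchanged genes. For IL-33 in STAT3-KO (11571 genes) it recovered 4%, 22%, 86% and 94% and called 7 unchanged genes. For genotype in control (11596 genes) these values were 2%, 16%, 84% and 92%, with 10 calls. For genotype with IL-33 (11579 genes) they were 0%, 14%, 72% and 86%, with 8 calls. For the interaction (11639 genes) they were 0%, 6%, 40% and 80%, with 5 calls. A planted list of 20 genes at 1.5-fold was called in each comparison and 0 other lists were. Simulated genes were drawn independently of each other, so these list results do not cover correlation between genes. In the real data the correlation estimated for mitochondrially encoded mRNAs was 0.396. Each simulated comparison changed only the 200 genes and the planted list. The real data had 4285 calls for IL-33 in WT, 6063 in STAT3-KO, 3876 for genotype with IL-33 and 1799 for the interaction. The Benjamini-Hochberg cut-off loosens as more genes change, so the simulated shares and false calls do not describe those 4 comparisons.

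Alternatives planned beforehand were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-of-ratios rescaling, quantile normalization, no trend in the prior variance, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Alternatives chosen after seeing the data were voom on the recovered reads, removal of a trend with gene length or with GC content in each library (loess with a span of 0.3), and protein-coding genes only. No library of the series was left out of the main tests.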

Results

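RNA was sequenced from 8 cultures of group 2 innate lymphoid cells (ILC2s), lymphocytes without antigen receptors that make type 2 cytokines, taken from the lungs of C57BL/6 mice after a short papain exposure. The cells were either WT (Stat3 floxed, no Cre) or STAT3-KO (Stat3 floxed with Vav-iCre, a recombinase made in blood cells). A comparison of the genotypes therefore cannot tell the loss of STAT3 apart from the presence of Vav-iCre. They grew for about 5 days in 10 ng/ml IL-2 and either received 10 ng/ml IL-33 for 2 more days or served as controls, whose medium during those days the labels do not describe. The 4 groups of WT control, STAT3-KO control, WT with IL-33 and STAT3-KO with IL-33 held 2 libraries each, and the labels do not say whether the replicates came from separate mice or cultures. Each library held between 15843685 and 19905817 reads, recovered from the steps of the values. At that depth 3 reads in a gene of 1 kb correspond to 0.151 to 0.189 FPKM (fragments per kilobase of gene, scaled to the depth of the library). The first principal component held 60.3% of the variance and the second 21.4%, and replicates correlated across genes with Pearson's r of 0.971 to 0.983 on the log2 scale. Unless stated otherwise, values are group means in FPKM with n = 2, and changes are differences of log2(FPKM + 1) with the standard error (SE) of limma. The largest rises and falls are named among called genes whose groups did not overlap and whose higher group averaged at least 5 FPKM, without unnamed gene models, ribosomal pseudogenes and microRNAs.

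Stat3, the gene deleted in the STAT3-KO cells, measured 41.7 and 50.7 FPKM in the WT control libraries and 49 and 55.3 in the WT libraries with IL-33. It measured 15.3 and 16 in the STAT3-KO control libraries and 8.03 and 9.69 in the STAT3-KO libraries with IL-33, so that each STAT3-KO library lay below each WT library. The labels do not name the floxed exons, and a value per gene need not reach 0 in deleted cells. Stat3 (ENSMUSG00000004040, GRCm38 chromosome 11, 100885098 to 100939540) differed in STAT3-KO from WT cells by -1.50 ± 0.15 in control (adjusted p = 0.00771) and by -2.43 ± 0.15 with IL-33 (adjusted p = 2.22e-05). IL-33 lowered it within STAT3-KO cells (-0.76 ± 0.15, adjusted p = 0.00305), whereas the difference in WT was 0.18 ± 0.15 (adjusted p = 0.37). The difference between those responses was -0.94 ± 0.21 (adjusted p = 0.0197). Without STAT3-KO control library 1 or 2 the control difference was -1.47 or -1.53 and missed the threshold. With the control libraries fitted alone it stayed at -1.50 but also missed the threshold. The difference between responses missed it without WT control library 1, STAT3-KO control library 1 or 2, WT IL-33 library 2 or STAT3-KO IL-33 library 1, and the fall within STAT3-KO cells was -0.30 and missed it once a trend with gene length was removed.

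**Figure D1:**
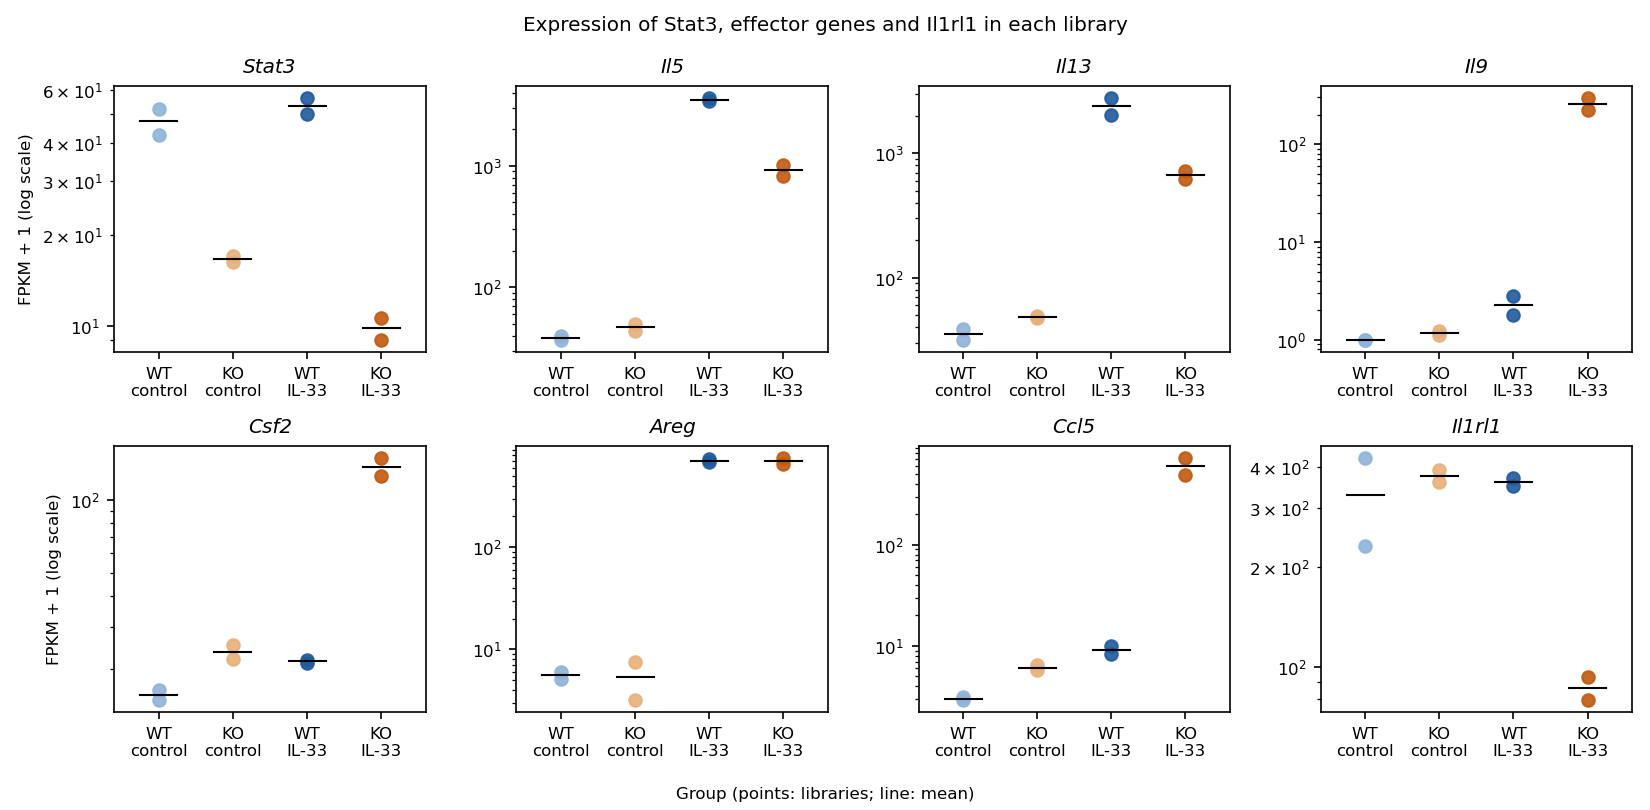
Expression of 8 genes in each library (points, FPKM + 1 on a log scale) by group on the horizontal axis, with lines at the mean of the 2 libraries of a group. Both STAT3-KO groups lie below both WT groups for Stat3, and with IL-33 Il5 averages 3500 FPKM in WT and 921 in STAT3-KO, while Il9 averages 1.29 and 258.

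The first comparison asks how WT ILC2s respond to IL-33, the alarmin that activates them through the receptor Il1rl1. Il5, the cytokine that drives eosinophil growth, rose from 37.2 ± 1.79 to 3500 ± 144 FPKM (SD, n = 2), a difference of 6.52 ± 0.13 (adjusted p = 4.1e-08). Il13, which drives mucus production, rose from 34.2 to 2402 FPKM (6.08 ± 0.16, adjusted p = 2.72e-07). Areg, a growth factor of tissue repair, rose from 4.55 to 704 FPKM (6.99 ± 0.32). Smaller rises were measured for Il4 (from 2.93 to 6.03 FPKM), Il9 (listed at 0 in both control libraries and at 1.29 with IL-33) and Csf2 (from 14.7 to 20.6 FPKM). Il6 (3.15 and 3.8 FPKM) and Il1rl1 (327 and 359.8) did not pass the threshold. Gata3, the lineage factor of ILC2s, fell from 459 to 285 FPKM.

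Beyond Areg, the largest rises were those of Tnfrsf8, which encodes CD30 (from 0.641 to 338 FPKM), Penk, the enkephalin precursor (from 0.478 to 179 FPKM), the basophil protease gene Mcpt8 (from 0.0632 to 103 FPKM) and the decoy receptor Il1r2 (from 2.94 to 367 FPKM). The largest falls were those of the sialyltransferase St3gal6 (from 39.1 to 0.338 FPKM) and the acyltransferase Lpcat2 (from 56.1 to 2.85 FPKM). The others were Ifi208 (from 16.2 to 0.344 FPKM), the immunoglobulin heavy chain gene Ighm (from 49 to 2.88 FPKM) and the T cell receptor segment Trbj2-7 (from 22.6 to 0.534 FPKM). Reads of receptor and immunoglobulin segments can be shared between near-identical segments, which leaves their levels uncertain. Receptor segments such as Trbj2-7 are far shorter than 1 kb, so a given FPKM stands for fewer reads there. The fall of Trbj2-7 may thus rest on few reads.

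Counts adjusted over the list alone are given where they differ from those over all genes, and list tests are those of limma's camera. Among the 15 effector cytokine genes, 11 rose and 2 fell (adjusted p = 8.92e-08, adjusted p = 0.0516 with an estimated correlation). Il10, a regulatory cytokine, was among them and rose from 0.145 to 40.2 FPKM. Of 9 chemokine genes, 4 rose and 0 fell (adjusted p = 0.00146, adjusted p = 0.197 with an estimated correlation). Among these were Cxcl3 (from 1.01 to 62.7 FPKM), Cxcl2 (from 0.216 to 7.2 FPKM) and Ccl5 (from 2.01 to 8.1 FPKM). In the ILC2 identity and receptor list, 4 of 27 genes rose and 14 fell (4 and 15 adjusted over the list alone; adjusted p = 0.0408, adjusted p = 0.205 with an estimated correlation). Il17rb, the IL-25 receptor, fell from 30.5 to 2.41 FPKM and Il7r, the IL-7 receptor, from 522 to 177 FPKM, while Il2ra, the high-affinity subunit of the IL-2 receptor, rose from 94.1 to 969.6 FPKM. STAT3 target genes rose in 8 of 12 cases and fell in 0 (9 and 1 adjusted over the list alone; adjusted p = 2.82e-06, adjusted p = 0.0511 with an estimated correlation). Socs3, a feedback inhibitor of STAT3, rose from 5.87 to 179 FPKM and Junb from 87.8 to 447 FPKM. NF-kB response genes rose in 14 of 22 cases and fell in 1 (14 and 2 adjusted over the list alone; adjusted p = 3.98e-07, adjusted p = 0.0724 with an estimated correlation). Ier3 (from 5.89 to 57.4 FPKM) and the inhibitor Nfkbia (from 200.5 to 561 FPKM) were among them. Co-stimulatory and inhibitory receptors and ligands rose in 13 of 20 cases and fell in 5 (15 and 5 adjusted over the list alone; adjusted p = 0.000226, adjusted p = 0.0841 with an estimated correlation). Tnfrsf9, a co-stimulatory receptor, rose from 2.61 to 141 FPKM and the inhibitory receptor Pdcd1 from 35.2 to 148 FPKM.

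Genes of glycolysis, the breakdown of glucose, rose in 17 of 24 cases and fell in 2 (19 and 2 adjusted over the list alone; adjusted p = 8.29e-09, adjusted p = 0.0516 with an estimated correlation). Ldha, lactate dehydrogenase A, rose from 460.2 to 1639.5 FPKM and the lactate exporter Slc16a3 from 28.1 to 129 FPKM. Of 22 genes of cholesterol synthesis, 12 rose and 0 fell (13 and 0 adjusted over the list alone; adjusted p = 2.82e-06, adjusted p = 0.0511 with an estimated correlation). Idi1 was among them (from 13.6 to 98.9 FPKM). The fatty acid list had 10 rises and 3 falls among 23 genes (10 and 4 adjusted over the list alone; adjusted p = 0.0156, adjusted p = 0.0954 with an estimated correlation). Its mean (0.69) and its median (-0.02) differed in sign. Its members Dgat2, Dgat1 and Plin2, which make or coat stored triglyceride, rose, Plin2 from 106 to 313 FPKM. Serine and folate genes rose in 8 of 19 cases and fell in 0 (9 and 0 adjusted over the list alone; adjusted p = 0.000226, adjusted p = 0.073 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, went from 87 to 169.8 FPKM. Methyltransferase genes fell in 11 of 25 cases and rose in 1 (adjusted p = 0.0479, adjusted p = 0.276 with an estimated correlation). Ehmt2 went from 18.2 to 8.62 FPKM. Mitochondrially encoded mRNAs fell in 7 of 10 cases and rose in 0 (0 and 9 adjusted over the list alone; adjusted p = 0.000545, adjusted p = 0.22 with an estimated correlation). The transcript mt-Co1 went from 6117 to 2129 FPKM. All genes with a symbol that starts with mt-, not only the list, together held 6.2% and 5.5% of all FPKM in the WT control libraries. They held 3.3% and 2.3% in the WT libraries with IL-33, against 6.1% to 7.1% in the STAT3-KO libraries.

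Of 31 cell cycle genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 1.3e-05, adjusted p = 0.0516 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 19.2 to 57.1 FPKM. The cell cycle inhibitor Cdkn1a also rose (from 60 to 227 FPKM) and the inhibitor Cdkn1b fell (from 13.5 to 4.72 FPKM). Genes of the unfolded protein response rose in 15 of 20 cases and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 1.31e-08, adjusted p = 0.0511 with an estimated correlation). The chaperone Hspa5 went from 152 to 314 FPKM. ATF4 target genes rose in 12 of 19 cases and fell in 2 (12 and 3 adjusted over the list alone; adjusted p = 0.000312, adjusted p = 0.0516 with an estimated correlation). Asns, asparagine synthetase, went from 27.5 to 75.7 FPKM. Stress and immediate-early genes rose in 5 of 13 cases and fell in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.0254, adjusted p = 0.205 with an estimated correlation). Atf3 went from 0.483 to 21.6 FPKM. Interferon-stimulated genes fell in 6 of 18 cases and rose in 1 (1 and 9 adjusted over the list alone; adjusted p = 0.0239, adjusted p = 0.113 with an estimated correlation). Gbp2 went from 84.4 to 15.3 FPKM and Irf9 from 39.5 to 13.1 FPKM.

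Lists that did not pass in WT were those of the methionine cycle (4 rose and 7 fell of 21, adjusted p = 0.832), the nuclear respiratory chain (7 and 3 of 45, 2 and 2 adjusted over the list alone, adjusted p = 0.0538) and the TCA cycle (4 and 3 of 22, adjusted p = 0.813). The same held for JAK-STAT components (6 and 8 of 21, 7 and 9 adjusted over the list alone, adjusted p = 0.964) and cell death (7 and 6 of 16, adjusted p = 0.104). Mean and median differed in sign for the methionine and TCA cycles, and the test for JAK-STAT components pointed up although mean and median were below 0. Single members passed in these lists, such as Ahcy, which clears S-adenosylhomocysteine (from 16.8 to 44.8 FPKM), and Sdha (from 171 to 108 FPKM).

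In total, 4285 of 11877 genes changed with IL-33 in WT at an adjusted p under 0.05, 1724 higher and 2561 lower by limma. Of these, 1789 changed by at least 2-fold on the scale of FPKM + 1. The split between directions depended on the scaling, with 2299 higher and 1863 lower after median-of-ratios rescaling, which moved the median of all genes from -0.14 to 0. Without the WT IL-33 library 1 or 2, 2618 or 2528 genes passed.

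The second comparison asks the same of STAT3-KO cells. IL-33 raised Il5 from 45.8 ± 4.83 to 921 ± 145 FPKM (SD, n = 2; 4.29 ± 0.13, adjusted p = 2.3e-07) and Il13 from 46.9 to 672 FPKM (3.81 ± 0.16). Il9, a growth factor of mast cells and ILC2s, rose from 0.169 to 258 FPKM (7.78 ± 0.24, adjusted p = 3.66e-07), and Csf2, the gene of GM-CSF, from 22.6 to 136 FPKM (2.53 ± 0.13). Areg rose from 4.33 to 697 FPKM and Il6 from 3.54 to 9.22 FPKM, while Il4 was at 2.84 and 2.66 FPKM without a call. Il1rl1 fell from 374 to 85.5 FPKM (-2.12 ± 0.24, adjusted p = 0.000186) and Gata3 from 515 to 173 FPKM. The largest rises beside Il9 and Areg were those of the neuropeptide gene Nts (listed at 0 in control, 399.7 FPKM with IL-33), the protease Mmp10 (from 0.0863 to 159 FPKM) and Gap43, a protein of nerve endings (from 4.77 to 604 FPKM). The largest falls were those of the granzyme Gzmd (from 29.4 FPKM to 0 in both libraries), the integrin Itgb3 (from 78.6 to 1.88 FPKM) and the stem cell factor receptor Kit (from 31.1 to 0.318 FPKM). Others were St3gal6 (from 38.2 to 0.695 FPKM) and the protease Ctsw (from 91.9 to 3.3 FPKM).

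Effector cytokines rose in 13 of 15 cases and fell in 1 in STAT3-KO cells (adjusted p = 2.64e-08, adjusted p = 0.13 with an estimated correlation). All 9 tested chemokine genes rose (adjusted p = 2.4e-07, adjusted p = 0.13 with an estimated correlation). Examples are Ccl5 (from 5.1 to 605 FPKM), Ccl3 (from 0.512 to 133 FPKM) and Cxcl3 (from 1.08 to 36.8 FPKM). Ccr7, a chemokine receptor in the dendritic cell list, rose from 15.1 to 319 FPKM alongside them. The ILC2 identity list had 21 falls and 4 rises among 27 genes (4 and 22 adjusted over the list alone; adjusted p = 1.94e-05, adjusted p = 0.13 with an estimated correlation). Il7r fell from 563 to 74 FPKM, Il17rb from 27.3 to 0.351 FPKM and the transcription factor Ets1 from 79.7 to 10.4 FPKM. STAT3 target genes rose in 7 of 12 cases and fell in 1 (adjusted p = 0.00381, adjusted p = 0.13 with an estimated correlation). Socs3 went from 2.96 to 15.6 FPKM and Myc from 86.4 to 221 FPKM. NF-kB response genes rose in 16 of 22 cases and fell in 2 (adjusted p = 2.15e-05, adjusted p = 0.13 with an estimated correlation). Nfkbia went from 216 to 834 FPKM, whereas Nfkb1 fell from 73.2 to 15.8 FPKM. Co-stimulatory and inhibitory receptors and ligands rose in 10 of 20 cases and fell in 4 (adjusted p = 0.00381, adjusted p = 0.131 with an estimated correlation). Tnfrsf9 went from 2.82 to 91 FPKM and Cd80, a ligand in this list, from 7.22 to 27.3 FPKM.

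Genes of the nuclear respiratory chain rose in 21 of 45 cases and fell in 3 (adjusted p = 7.08e-05, adjusted p = 0.364 with an estimated correlation). Atp5b, a subunit of ATP synthase, went from 442 to 815 FPKM. Those of the TCA cycle rose in 13 of 22 cases and fell in 3 (adjusted p = 0.00381, adjusted p = 0.13 with an estimated correlation). Fh1, fumarase, went from 61.4 to 103 FPKM. Glycolysis genes rose in 15 of 24 cases and fell in 4 (adjusted p = 0.000966, adjusted p = 0.13 with an estimated correlation). Pgk1 went from 185 to 476 FPKM, while Pdk1, which inhibits pyruvate dehydrogenase, fell from 21 to 3.87 FPKM. Serine and folate genes rose in 8 of 19 cases and fell in 1 (adjusted p = 0.00381, adjusted p = 0.13 with an estimated correlation). Psat1 went from 26.5 to 77.4 FPKM. ATF4 targets rose in 9 of 19 cases and fell in 3 (adjusted p = 0.0206, adjusted p = 0.13 with an estimated correlation). Asns went from 20.6 to 69.2 FPKM. The unfolded protein response had 10 rises and 1 fall among 20 genes (adjusted p = 0.00381, adjusted p = 0.13 with an estimated correlation). Hspa5 went from 141 to 244 FPKM. Stress and immediate-early genes rose in 7 of 13 cases and fell in 3 (adjusted p = 0.00887, adjusted p = 0.149 with an estimated correlation). Atf3 went from 0.201 to 89 FPKM.

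No call was made in STAT3-KO cells for the methionine cycle (8 rose and 5 fell of 21, adjusted p = 0.336), methyltransferases (3 and 13 of 25, adjusted p = 0.0624) and mitochondrially encoded mRNAs (0 and 3 of 10, adjusted p = 0.184). The same was true of the fatty acid list (9 and 4 of 23, adjusted p = 0.0586), cholesterol synthesis (6 and 4 of 22, adjusted p = 0.167) and JAK-STAT components (5 and 10 of 21, 5 and 11 adjusted over the list alone, adjusted p = 0.487). Also without a call were the cell cycle (7 and 10 of 31, adjusted p = 0.665), interferon-stimulated genes (8 and 8 of 18, adjusted p = 0.759) and cell death (8 and 6 of 16, adjusted p = 0.167). For interferon-stimulated genes the test pointed up with mean and median below 0. Members that passed included the DNA methyltransferase Dnmt1 (from 27.7 to 4.72 FPKM), the kinase Jak1 (from 116 to 33.4 FPKM), the replication gene Mcm2 (from 36.5 to 13.1 FPKM) and the sterol sensor partner Insig1 (from 29.1 to 19.7 FPKM).

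In STAT3-KO cells 6063 genes changed with IL-33 by limma, 2425 higher and 3638 lower, 2871 of them by at least 2-fold. After median-of-ratios rescaling the split was 3140 higher and 2761 lower, with the median of all genes moving from -0.18 to -0.01.

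The third comparison asks how STAT3-KO control cells differ from WT control cells. Among the largest rises in STAT3-KO was that of Tbx21, the transcription factor T-bet of NK cells and ILC1 (from 3.58 ± 0.761 to 20.3 ± 0.954 FPKM, SD, n = 2; 2.23 ± 0.22, adjusted p = 0.0078). The others were those of the T cell receptor segment Trbd1 (from 7.74 to 38 FPKM), Sema6d (from 1.64 to 7.28 FPKM), Gzmd (from 8.63 to 29.4 FPKM) and Tnfsf8, the ligand of CD30 (from 11.1 to 32.6 FPKM, 1.48 ± 0.14). The largest falls beside Stat3 were those of the water and glycerol channel Aqp9 (from 11.7 to 1.88 FPKM, -2.17 ± 0.28, adjusted p = 0.018), the keratin Krt80 (from 16.8 to 3.82 FPKM), Troap (from 10.2 to 3.09 FPKM) and Lrrc25 (from 11.1 to 3.85 FPKM). None of the other fixed genes passed, with Il5 at 37.2 FPKM in WT and 45.8 in STAT3-KO, Il13 at 34.2 and 46.9, and Gata3 at 459 and 515. Gzmd and Trbd1 have near-identical relatives, so that part of their reads may belong elsewhere. Trbd1 is also far shorter than 1 kb, so that its rise may rest on few reads.

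Cell cycle genes were lower as a group in STAT3-KO control cells (1 of 31 lower and 0 higher, 2 and 12 adjusted over the list alone; adjusted p = 2.2e-10, adjusted p = 0.0917 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, was the member past the threshold (from 94.4 to 47.2 FPKM). Interferon-stimulated genes were also lower (1 of 18 lower and 0 higher, 0 and 2 adjusted over the list alone; adjusted p = 0.00207, adjusted p = 0.199 with an estimated correlation). Irf9, part of the interferon-activated transcription complex, went from 39.5 to 23.1 FPKM. The NK cell and ILC1 markers were higher (1 of 4 higher and 0 lower; adjusted p = 0.00207, adjusted p = 0.251 with an estimated correlation). Tbx21 was the member past the threshold, at 2.23 against 0.58 for Ctsw, 0.49 for Gzma and 0.25 for Prf1. Mitochondrially encoded mRNAs were higher as a group (0 of 10 past the threshold; adjusted p = 0.0204, adjusted p = 0.631 with an estimated correlation). The level of mt-Co1 was 6117 FPKM in WT and 7209 in STAT3-KO. In the ILC2 identity list Il10ra was higher (from 7.74 to 17.5 FPKM), and Ly6a, the stem cell antigen Sca-1, and Thy1 were lower (from 235 to 122 FPKM and from 39.6 to 20.5 FPKM). This made 1 higher and 2 lower of 27 (4 and 5 adjusted over the list alone; adjusted p = 0.344). Tnfsf8 and Cd81 were the 2 higher members of the 20 co-stimulatory genes (4 and 2 adjusted over the list alone; adjusted p = 0.158). Cpa3, the mast cell carboxypeptidase, fell from 312 to 126 FPKM.

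The other 17 gene lists had 0 members past the threshold over all genes, and none was called as a list. Adjusted over the list alone, 1 effector cytokine, 1 chemokine, 2 NF-kB genes and 1 ATF4 target were higher, and 2 STAT3 targets, 1 JAK-STAT component and 1 stress gene were lower. List p values were 0.355 for effector cytokines, 0.427 for chemokines, 0.979 for STAT3 targets, 0.857 for JAK-STAT components and 0.0682 for NF-kB genes. They were 0.227 for glycolysis, 0.158 for cholesterol synthesis, 0.971 for the fatty acid list, 0.523 for the TCA cycle and 0.355 for the nuclear respiratory chain. For the remaining lists they were 0.695 for the methionine cycle, 0.344 for serine and folate genes, 0.695 for methyltransferases, 0.979 for ATF4 targets, 0.253 for the unfolded protein response, 0.779 for cell death and 0.709 for stress genes, all adjusted. Mean and median differed in sign for the methionine cycle, STAT3 targets, JAK-STAT components, ATF4 targets and cell death.

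In all, 55 genes differed between the genotypes in control by limma, 30 higher and 25 lower in STAT3-KO, with 43 at 2-fold or more and 1106 at an unadjusted p under 0.05. The count fell to 7, 1 and 1 without WT control library 1, STAT3-KO control library 1 or STAT3-KO control library 2, and to 30, 30, 36 and 36 without 1 of the IL-33 libraries. It was 0 when the 4 control libraries were fitted alone.

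The fourth comparison sets STAT3-KO against WT cells after IL-33. STAT3-KO cells had less Il5 (3500 ± 144 FPKM in WT and 921 ± 145 in STAT3-KO, SD, n = 2; -1.93 ± 0.13, adjusted p = 3.24e-05), Il13 (2402 and 672; -1.82 ± 0.16) and Il4 (6.03 and 2.66). They had more Il9 (1.29 and 258; 6.84 ± 0.24, adjusted p = 2.8e-06), Csf2 (20.6 and 136; 2.66 ± 0.13) and Il6 (3.8 and 9.22). Areg differed by -0.02 ± 0.32 (adjusted p = 0.981), at 704 and 697 FPKM. Il1rl1 (359.8 and 85.5) and Gata3 (285 and 173) were lower in STAT3-KO. The largest rises beside Il9 were those of the chemokines Ccl5 (from 8.1 to 605 FPKM), Ccl3 (from 1.82 to 133 FPKM), Ccl9 (from 3.58 to 127 FPKM) and Cx3cl1 (from 0.186 to 26.6 FPKM). The largest falls were those of Mcpt8 (from 103 to 0.123 FPKM), the cytotoxic protease Gzmb (from 81.2 to 0.107 FPKM) and Aqp9 (from 111 to 1.4 FPKM). The others were Ly6c1 (from 40.8 to 0.0716 FPKM) and Ero1l, an oxidase of the endoplasmic reticulum (from 1276 to 73 FPKM).

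Chemokine genes were higher in STAT3-KO with IL-33 in 7 of 9 cases and lower in 2 (adjusted p = 0.000687, adjusted p = 0.282 with an estimated correlation). Ccl4 (from 0.224 to 8.47 FPKM) and Cxcl10 (from 0.34 to 9.72 FPKM) were among the higher ones. The chemokine receptor Ccr7, in the dendritic cell list, was higher beside them (from 118 to 319 FPKM). ILC2 identity genes were lower in 17 of 27 cases and higher in 4 (5 and 17 adjusted over the list alone; adjusted p = 9.05e-05, adjusted p = 0.107 with an estimated correlation). Those lower included Thy1 (from 34.9 to 2.46 FPKM), Ly6a (from 983 to 113 FPKM), Ets1 (from 72.8 to 10.4 FPKM) and the inhibitory receptor Klrg1 (from 914 to 289 FPKM). Cell cycle genes were lower in 24 of 31 cases and higher in 1 (1 and 25 adjusted over the list alone; adjusted p = 6.13e-11, adjusted p = 0.0832 with an estimated correlation). Birc5, survivin, was at 79.9 FPKM in WT and 25.6 in STAT3-KO, and the replication licensing gene Cdc6 at 25.4 and 7.22. Ccnd2 was the higher member (101 and 231). Effector cytokines split into 6 higher and 6 lower of 15 (6 and 6 adjusted over the list alone; adjusted p = 0.845). They had a mean of 0.23 and a median of -0.19, and the test pointed down.

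Mitochondrially encoded mRNAs were higher in STAT3-KO with IL-33 in 7 of 10 cases and lower in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.000632, adjusted p = 0.367 with an estimated correlation). The level of mt-Co1 was 2129 FPKM in WT and 5461 in STAT3-KO. Nuclear respiratory chain genes were higher in 10 of 45 cases and lower in 1 (adjusted p = 0.0159, adjusted p = 0.622 with an estimated correlation). TCA cycle genes were higher in 9 of 22 cases and lower in 1 (11 and 2 adjusted over the list alone; adjusted p = 0.00931, adjusted p = 0.268 with an estimated correlation). Suclg2 went from 15.9 to 33.2 FPKM. Glycolysis genes were lower in 11 of 24 cases and higher in 4 (5 and 12 adjusted over the list alone; adjusted p = 0.00152, adjusted p = 0.268 with an estimated correlation). Pkm, pyruvate kinase, went from 741 to 393 FPKM and Slc16a3 from 129 to 40 FPKM. Cholesterol synthesis genes were lower in 12 of 22 cases and higher in 0 (1 and 12 adjusted over the list alone; adjusted p = 0.000443, adjusted p = 0.0964 with an estimated correlation). Insig1 went from 69.4 to 19.7 FPKM. Unfolded protein response genes were lower in 10 of 20 cases and higher in 1 (1 and 11 adjusted over the list alone; adjusted p = 0.000134, adjusted p = 0.0964 with an estimated correlation). The sensor Ern1 went from 18.4 to 4.57 FPKM and the chaperone Hsp90b1 from 313 to 213 FPKM. Among STAT3 targets 3 of 12 were higher and 4 lower (3 and 4 adjusted over the list alone; adjusted p = 0.649). The mean was -0.60 and the median 0.09. Socs3 (from 179 to 15.6 FPKM) and Hif1a, the hypoxia factor (from 184 to 26.2 FPKM), were lower, and Bcl2l1, a survival gene (from 107 to 295 FPKM), was higher.

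Not called as lists after IL-33 were the methionine cycle (7 higher and 2 lower of 21, 8 and 2 adjusted over the list alone, adjusted p = 0.296), serine and folate genes (4 and 4 of 19, 4 and 5 adjusted over the list alone, adjusted p = 0.65) and methyltransferases (4 and 3 of 25, adjusted p = 0.77). So were the fatty acid list (5 and 7 of 23, 6 and 8 adjusted over the list alone, adjusted p = 0.272), JAK-STAT components (5 and 9 of 21, adjusted p = 0.207) and NF-kB response genes (7 and 5 of 22, adjusted p = 0.639). The same held for co-stimulatory genes (6 and 6 of 20, adjusted p = 0.649) and interferon-stimulated genes (8 and 4 of 18, adjusted p = 0.189). Nor was a call reached by ATF4 targets (2 and 6 of 19, 3 and 7 adjusted over the list alone, adjusted p = 0.296), cell death (4 and 3 of 16, adjusted p = 0.331) or stress genes (5 and 2 of 13, 6 and 2 adjusted over the list alone, adjusted p = 0.115). Members with large differences were Dnmt1 (from 27.9 to 4.72 FPKM), the amino acid transporter Slc7a8 (from 35.3 to 6.7 FPKM), Cd83 (from 0.429 to 26 FPKM), Gbp2 (from 15.3 to 80.6 FPKM) and the triglyceride enzyme Dgat1 (from 69.2 to 21.4 FPKM).

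With IL-33, 3876 genes differed between the genotypes by limma, 1932 higher and 1944 lower in STAT3-KO, 1569 of them by at least 2-fold. The count was 2381 without WT IL-33 library 1, 2141 without WT IL-33 library 2 and 2530 without STAT3-KO IL-33 library 1.

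The fifth comparison tests whether the response to IL-33 itself differed between STAT3-KO and WT cells, as the difference of the 2 responses. Il5 went from 37.2 to 3500 FPKM in WT and from 45.8 to 921 FPKM in STAT3-KO, a difference of responses of -2.22 ± 0.18 (adjusted p = 0.00036). That of Il13 was -2.27 ± 0.23 (adjusted p = 0.00103). The response was larger in STAT3-KO for Il9 (6.61 ± 0.34, adjusted p = 7.83e-05) and Csf2 (2.07 ± 0.19). Il1rl1 went from 327 to 359.8 FPKM in WT and from 374 to 85.5 FPKM in STAT3-KO (-2.32 ± 0.33, adjusted p = 0.0041). Gata3 fell further in STAT3-KO (-0.88 ± 0.11). Il4, Il6 and Areg did not pass, with differences of -0.90 ± 0.28, 1.02 ± 0.36 and 0.16 ± 0.45. Ccl3, Ccl5, Ccl9 and Foxs1 had the largest positive differences beside Il9. Gzmb (-6.89 ± 0.23), Mcpt8 (-6.45 ± 0.29), Ly6c1, Ero1l and Serinc5 had the largest negative ones. Gzmb rose from 10.6 to 81.2 FPKM in WT and fell from 17.3 to 0.107 FPKM in STAT3-KO. Likewise Ero1l rose from 291 to 1276 FPKM and fell from 320.4 to 73 FPKM.

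**Figure D2:**
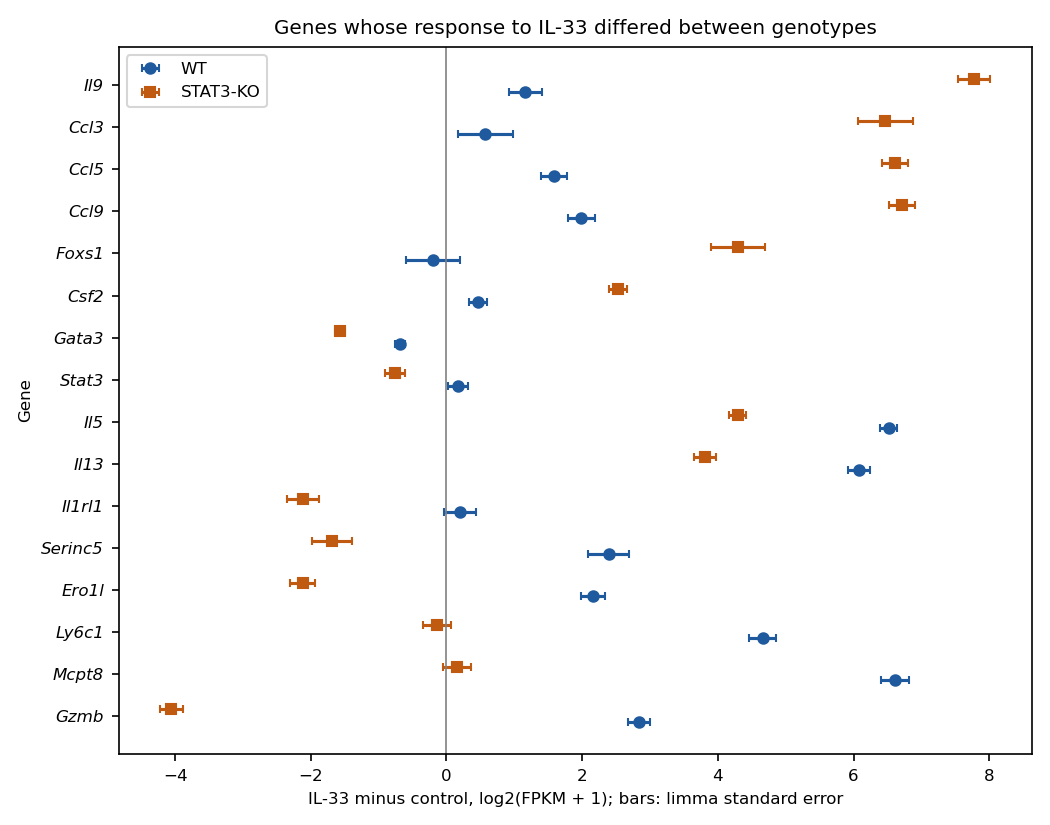
Response to IL-33 (horizontal axis, difference of log2(FPKM + 1) between IL-33 and control, bars are limma standard errors) in WT (circles) and STAT3-KO (squares) for the fixed genes past the threshold of the interaction test and the 5 largest differences in each direction (vertical axis). Il9 changed by 1.16 in WT and 7.78 in STAT3-KO, and Gzmb by 2.84 and -4.05.

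By list, the response of chemokines was larger in STAT3-KO (6 of 9 higher and 1 lower, 7 and 2 adjusted over the list alone; adjusted p = 0.000428, adjusted p = 0.204 with an estimated correlation). Differences were 3.03 ± 0.31 for Ccl4 and 2.41 ± 0.30 for Ccl22. ILC2 identity genes responded lower in STAT3-KO in 16 of 27 cases and higher in 2 (3 and 17 adjusted over the list alone; adjusted p = 4.19e-06, adjusted p = 0.139 with an estimated correlation). Ets1 differed by -2.37 and Thy1 by -2.45. Cell cycle genes did so in 10 of 31 cases and the reverse in 1 (1 and 19 adjusted over the list alone; adjusted p = 2.55e-06, adjusted p = 0.139 with an estimated correlation). Mcm2 differed by -1.40 and Mcm4 by -1.21. Differences were negative for 5 of 22 cholesterol genes and positive for 0 (0 and 6 adjusted over the list alone; adjusted p = 0.00509, adjusted p = 0.147 with an estimated correlation). Insig1 differed by -1.96. They were negative for 8 of 24 glycolysis genes and positive for 2 (3 and 11 adjusted over the list alone; adjusted p = 0.00509, adjusted p = 0.239 with an estimated correlation). Pkm differed by -0.79. Values were negative for 6 of 20 unfolded protein response genes and positive for 1 (1 and 7 adjusted over the list alone; adjusted p = 0.002, adjusted p = 0.139 with an estimated correlation). Ern1 differed by -1.95. NK cell and ILC1 markers had 2 negative and 0 positive differences among 4 (0 and 3 adjusted over the list alone; adjusted p = 0.0114, adjusted p = 0.204 with an estimated correlation). Ctsw differed by -3.99.

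Among positive list differences, mitochondrially encoded mRNAs had 3 higher and 0 lower of 10 (4 and 0 adjusted over the list alone; adjusted p = 0.0114, adjusted p = 0.475 with an estimated correlation). The transcript mt-Co1 differed by 1.14. The nuclear respiratory chain had 7 higher and 1 lower of 45 (adjusted p = 0.00509, adjusted p = 0.574 with an estimated correlation). Uqcrc1 differed by 0.83. The TCA cycle had 5 higher and 1 lower of 22 (8 and 1 adjusted over the list alone; adjusted p = 0.00509, adjusted p = 0.204 with an estimated correlation). Fh1 differed by 0.78. Interferon-stimulated genes had 7 higher and 1 lower of 18 (7 and 2 adjusted over the list alone; adjusted p = 0.0133, adjusted p = 0.198 with an estimated correlation). Gbp2 went from 84.4 to 15.3 FPKM in WT and from 49.3 to 80.6 FPKM in STAT3-KO. Stress and immediate-early genes had 4 higher and 2 lower of 13 (5 and 2 adjusted over the list alone; adjusted p = 0.0444, adjusted p = 0.338 with an estimated correlation). Egr2 differed by 1.95.

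Not called were effector cytokines (4 higher and 5 lower of 15, 6 and 6 adjusted over the list alone, adjusted p = 0.959), the methionine cycle (adjusted p = 0.306), serine and folate genes (adjusted p = 0.959) and methyltransferases (adjusted p = 0.727). Nor were the fatty acid list (1 and 7 of 23, 6 and 8 adjusted over the list alone, adjusted p = 0.318) and STAT3 targets (3 and 4 of 12, 3 and 5 adjusted over the list alone, adjusted p = 0.484). The threshold was also missed by JAK-STAT components (3 and 4 of 21, 4 and 6 adjusted over the list alone, adjusted p = 0.255) and NF-kB genes (2 and 4 of 22, 4 and 4 adjusted over the list alone, adjusted p = 0.959). It was missed by co-stimulatory genes (3 and 5 of 20, 6 and 5 adjusted over the list alone, adjusted p = 0.829), ATF4 targets (0 and 2 of 19, 0 and 0 adjusted over the list alone, adjusted p = 0.347) and cell death (adjusted p = 0.415). Signs of mean, median or test differed for effector cytokines, serine and folate genes, NF-kB genes and cell death. Socs3 (-2.63 ± 0.21), Hif1a (-2.89 ± 0.35), Dnmt1 (-2.48 ± 0.19) and Jak1 (-1.82 ± 0.21) were members with large negative differences.

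The interaction test called 1799 genes by limma, 798 with a higher and 1001 with a lower response in STAT3-KO, and 1255 differed by at least 2-fold. Of the 1799, 316 had been called in both genotypes in the same direction with the larger change in STAT3-KO, 110 in both with the larger change in WT and 165 in both in opposite directions. In WT alone 340 had been called, in STAT3-KO alone 851 and in neither 17. The count was 1125 without WT control library 1, 955 and 890 without STAT3-KO control library 1 or 2, and 915 and 857 without WT IL-33 library 1 or 2. It was 1125 without STAT3-KO IL-33 library 1 and 1149 with no filter on low values.

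**Figure D3:**
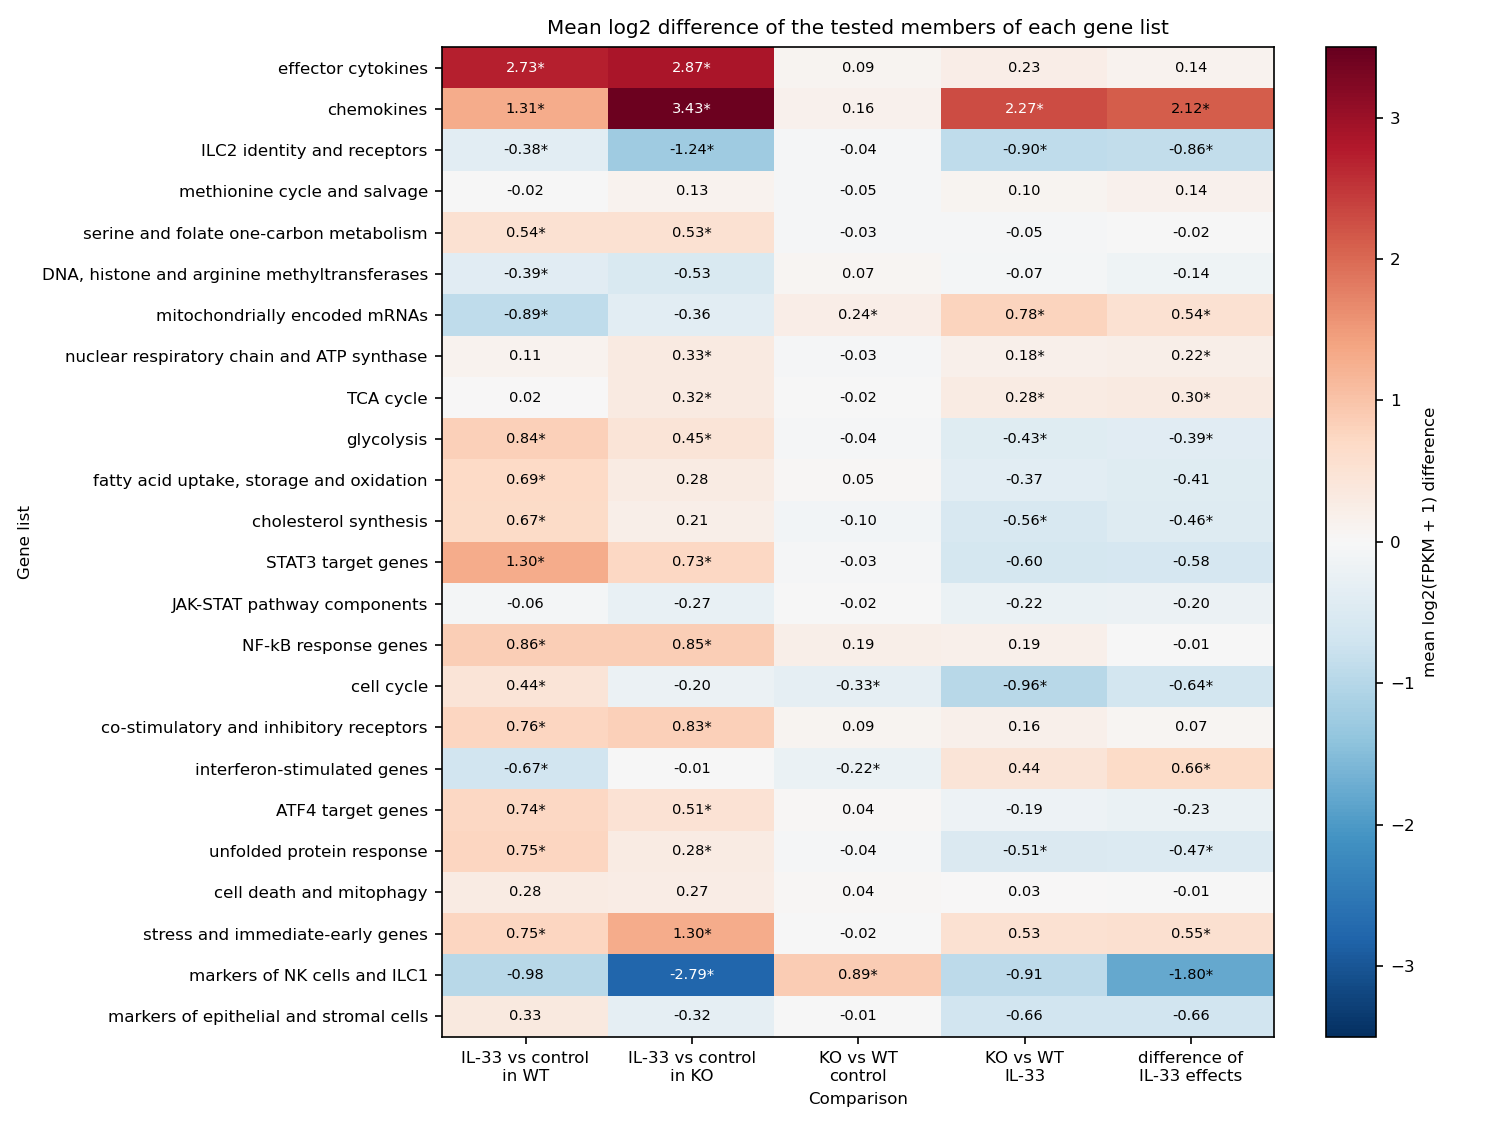
Mean difference of log2(FPKM + 1) of the tested members of each gene list (vertical axis) in the 5 comparisons (horizontal axis), with an asterisk where camera with a preset correlation of 0.01 gave an adjusted p under 0.05. The chemokine mean is 1.31 in WT and 3.43 in STAT3-KO, and no list passed in any comparison with an estimated correlation.

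Across 11877 genes, the responses to IL-33 in WT and STAT3-KO, which share no libraries, correlated with Pearson's r of 0.649 and Spearman's rho of 0.601, where genes are not independent replicates. Both responses called 1097 genes higher, against 352 for independent lists, and 1695 lower, against 784.5. The genotype differences in control and with IL-33 correlated with r of 0.151 and rho of 0.101, where r was 0.25 or 0.031 without WT control library 1 or 2. Both called 20 genes higher, against 4.88 for independent lists, and 14 lower, against 4.09, while 5 had opposite directions, counts that rest on the 55 genes called in control.

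Markers of other cell types were low, with exceptions that moved with IL-33 or genotype. Of the T cell list, Cd3g changed with IL-33 in WT (from 6.75 to 4.2 FPKM) and STAT3-KO (from 8.76 to 5.6 FPKM). Cd3e was at 0.212 FPKM in WT and 0.122 in STAT3-KO with IL-33. The NK cell and ILC1 markers fell with IL-33 in STAT3-KO in 4 of 4 cases (adjusted p = 0.00381, adjusted p = 0.13 with an estimated correlation). Ctsw went from 91.9 to 3.3 FPKM. In WT 2 of 4 fell (adjusted p = 0.0652). Between the genotypes with IL-33 1 was higher and 2 lower (1 and 3 adjusted over the list alone; adjusted p = 0.269). Of the B cell list, Ighm fell and Cd79b rose with IL-33, Cd79b from 3.06 to 20.4 FPKM in STAT3-KO. The macrophage gene Cd68 rose in WT (from 0.603 to 5.67 FPKM). Lyz2 was at 0.439 FPKM in WT and 0 in STAT3-KO with IL-33. Of the 2 tested genes of dendritic cells, Xcr1 rose from 2.92 to 5.88 FPKM in WT, and Ccr7 rose there as well. Of the mast cell and basophil list, Cpa3 fell with IL-33 in WT (from 312 to 38.2 FPKM) and STAT3-KO (from 126 to 7.51 FPKM). Mcpt8, the other tested member, rose in WT (from 0.0632 to 103 FPKM) and was at 0 and 0.123 FPKM in STAT3-KO without a call. No granulocyte marker was tested, Ngp being at most 0.439 FPKM. Of 3 epithelial and stromal genes, Pecam1 and Krt18 rose in WT, and Epcam fell in STAT3-KO (from 6.61 to 0.386 FPKM). List p values were 0.218 in WT, 0.665 in STAT3-KO, 0.971 between the genotypes in control, 0.395 between them with IL-33 and 0.354 for the interaction, all adjusted. For these genes the test in control pointed up with mean and median below 0, and in STAT3-KO mean and median differed in sign. Hba-a1, a hemoglobin gene with a near-identical copy, fell in WT (from 18.9 to 4.15 FPKM) and STAT3-KO. Xist, a sex-linked gene, fell with IL-33 in WT (from 4.59 to 1.73 FPKM) and STAT3-KO (from 6.29 to 1.89 FPKM) and did not differ past the threshold between the genotypes.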

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

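Of the tests in this part, the one against nuclear genes of like GC content and length was written before its result was seen. Those of scaling, single libraries and other cell types were chosen only after the result was seen.

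The results gathered here are those whose response to IL-33 differed between STAT3-KO and WT by limma's interaction test, given as STAT3-KO response minus WT response on the log2 scale. The count of such genes was 1799. Among list means, the difference was 2.12 for chemokines, -0.86 for ILC2 identity, 0.54 for mitochondrially encoded mRNAs, 0.22 for the nuclear respiratory chain, 0.30 for the TCA cycle and -0.39 for glycolysis. It was -0.46 for cholesterol synthesis, -0.64 for the cell cycle, 0.66 for interferon-stimulated genes, -0.47 for the unfolded protein response, 0.55 for stress genes and -1.80 for NK cell and ILC1 markers. None of these 12 list calls passed with an estimated correlation, where the lowest adjusted p was 0.139.

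Among the fixed genes the difference was -0.94 for Stat3, -2.22 for Il5, -2.27 for Il13, 6.61 for Il9, 2.07 for Csf2, -2.32 for Il1rl1 and -0.88 for Gata3. The largest positive differences were 5.90 for Ccl3, 5.02 for Ccl5, 4.73 for Ccl9 and 4.49 for Foxs1 beside Il9, and the largest negative ones -6.89 for Gzmb, -6.45 for Mcpt8, -4.80 for Ly6c1, -4.28 for Ero1l and -4.08 for Serinc5. Metabolic genes had differences of 1.14 for mt-Co1, 0.88 for mt-Nd4, 0.83 for Uqcrc1, 0.68 for Atp5a1, 0.77 for Pdhb, 0.78 for Fh1, -0.83 for Eno1, -0.79 for Pkm, -1.96 for Insig1 and -1.07 for Sc5d. Differences in the remaining lists were -2.37 for Ets1, -2.45 for Thy1, -1.21 for Mcm4, -1.40 for Mcm2, 3.08 for Gbp2, 1.28 for Irf9, -1.95 for Ern1, -0.98 for Dnajc3, 1.95 for Egr2, 0.72 for Btg2, -3.99 for Ctsw and -1.98 for Prf1.

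With IL-33, 7 of 10 mitochondrially encoded mRNAs were lower in WT than in STAT3-KO and 0 higher, with a mean STAT3-KO minus WT difference of 0.78 (adjusted p = 0.000632, adjusted p = 0.367 with an estimated correlation). Scaling between libraries is argued against, since the 6075 nuclear genes of at least 5 FPKM had a median difference of 0.0748 (95% bootstrap interval 0.0593 to 0.0919), and so is a single library, since leaving out any of the 4 IL-33 libraries left at least 0.59 (without WT IL-33 library 2). GC content or length bias is argued against by the 15 tested nuclear genes whose GC content (34.1% to 39.9%) and length lie in the range of the 10 mitochondrial ones, whose median difference was 0.00476 (95% bootstrap interval -0.138 to 0.178), against 0.74 for the mitochondrial list. These 15 genes are fewer than the 20 first asked for, a minimum lowered to 5 after their number was seen, and they were not matched for abundance. The bootstrap intervals resample genes and do not cover the spread between libraries. A difference in cell stress between the cultures remains open, since unfolded protein response genes were lower in STAT3-KO in the same comparison (10 of 20 lower and 1 higher; adjusted p = 0.000134, adjusted p = 0.0964 with an estimated correlation) and stress genes had 5 higher and 2 lower of 13 (adjusted p = 0.115), as do RNA quality, which was not tested, and the STAT3 genotype, the biological reading and a hypothesis.

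Il9 and 7 of 9 chemokine mRNAs were higher in STAT3-KO than in WT with IL-33, and Cxcl2 and Cxcl3 were lower (chemokine list, adjusted p = 0.000687, adjusted p = 0.282 with an estimated correlation). Macrophages or monocytes among the STAT3-KO cells are argued against, since their 5 markers in the table had a median of 0.249 FPKM there, with Lyz2 at 0, Cd14 at 0.249 and Cd68 at 4.19 (5.67 in WT), against 133 for Ccl3. Dendritic cells cannot be told apart from a change within the ILC2s, since their 6 markers had a median of only 0.552 FPKM (Itgax at 0.129, Flt3 at 0.00911, Xcr1 at 4.1 against 5.88 in WT), but Zbtb46 (0.224 in WT and 0.975 in STAT3-KO), Ccr7 (118 and 319), Cd83 (0.429 and 26) and H2-Eb1 (39.5 and 290.2) lay higher in STAT3-KO. T cells are argued against by a median of 0.0968 FPKM over 10 markers, against 258 for Il9, although Cd3g was at 5.6 (4.2 in WT). The STAT3 genotype stays open as a biological explanation, as a hypothesis found and tested on the same data, and a pattern of sorting or culture that went with genotype was not tested.

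Tbx21 was higher in STAT3-KO than in WT control cells by 2.23, a call that was lost without STAT3-KO control library 1 or 2, with the control libraries fitted alone and with a pseudocount of 0.1. NK cells or ILC1 among the STAT3-KO cells are argued against by the receptors Ncr1 and Klrb1c, which mark these cells. They were at 0 and 0.304 FPKM in STAT3-KO control, against 20.3 for Tbx21. The other 9 markers in the table differed by at most 0.831 (Klrd1). Of these, only Ctsw, Gzma and Prf1 had at least 1 FPKM in at least 2 libraries. Low levels keep differences of log2(FPKM + 1) small, so the differences of the rest cannot decide. As a list, the markers were called higher in STAT3-KO control by camera (adjusted p = 0.00207, adjusted p = 0.251 with an estimated correlation). Other cytotoxic genes were abundant in both genotypes without a call, Ctsw at 60.9 and 91.9 FPKM and Gzmb at 10.6 and 17.3, while Gzmd and Gzme were called higher, so that a change of such genes within the ILC2s stays open. An effect of the Vav-iCre transgene, which the labels give for STAT3-KO cells alone, was not tested and stays open beside the loss of STAT3, the biological reading and a hypothesis.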

How the results depend on the processing

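The alternatives of voom on recovered reads, gene length trend removed, GC content trend removed and protein-coding genes only were chosen after seeing the data, and the others were planned. Over the alternatives other than left-out libraries, 97.5% of 5851 values for reported genes and 92.8% of 1526 values for list means kept their side of the threshold. Those past the threshold also kept their direction. Values that missed the threshold in the main fit and in the alternative count as kept, whatever their direction. Many of the genes were picked for large changes or small p values in the main fit of the same data, which favors high shares. The shares also pool the 5 comparisons. With 1 library left out, these shares were 94% of 3984 and 96.2% of 960, where the lone library of a group is assumed to vary like the other groups. With an estimated correlation per list, 0 gene lists passed in each of the 5 comparisons.

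The number of genes that differed by genotype in control was 34 with a pseudocount of 0.1 and 87 among protein-coding genes, where the cause was not tested, and 0 in a fit of only the 4 control libraries, which leaves 2 residual degrees of freedom. In that fit Stat3 kept its difference of -1.50 in control but missed the threshold. The interaction called 1149 genes with no filter on low values, and IL-33 in STAT3-KO called 3803 with a mean FPKM of at least 5, which tests fewer genes. With the gene length trend removed, Stat3 changed by -0.30 with IL-33 in STAT3-KO and missed the threshold, and the cause was not tested. The correlation of the IL-33 responses was 0.688 with a mean FPKM of at least 5.

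With 1 library left out, the count ranged from 2528 to 4344 for IL-33 in WT, from 4245 to 6244 for IL-33 in STAT3-KO, from 1 to 43 for genotype in control, from 2141 to 4085 for genotype with IL-33 and from 857 to 2048 for the interaction. Called lists ranged from 2 to 5 for genotype in control. The Stat3 difference ranged from -1.64 to -1.36 in control and from -1.07 to -0.80 for the interaction. The correlation ranged from 0.581 to 0.679 for the IL-33 responses and from 0.031 to 0.25 for the genotype differences.

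The replicate number as a block gave 4271, 6015, 37, 3813 and 1827 genes in the order of the comparisons above, and deviations from the group means correlated by only -0.062 to 0.045 between groups, so that no pairing is seen. Voom gave 4559, 6090, 46, 4047 and 2007. Depth limits genes of low expression, since 3 reads in a gene of 1 kb are 0.151 to 0.189 FPKM.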

Other observations

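The 4 gene families in this part were chosen after their values were seen. Their members are counted by the test of each gene over all genes, and no test of a family is given. Of all 11877 tested genes, 1724 rose and 2561 fell with IL-33 in WT, and 2425 rose and 3638 fell in STAT3-KO. By genotype with IL-33, 1932 were higher and 1944 lower in STAT3-KO. The interaction called 798 higher and 1001 lower, and genotype in control 30 higher and 25 lower. Of 9 tested genes of the MHC class II pathway, which presents antigen to T helper cells, 6 rose and 1 fell with IL-33 in WT. In STAT3-KO 7 rose and 0 fell. With IL-33, 8 were higher in STAT3-KO and 0 lower. H2-Eb1 was at 39.5 ± 0.754 FPKM in WT and 290.2 ± 25.4 in STAT3-KO (SD, n = 2), a difference of 2.84 ± 0.16 by limma. H2-Aa was at 26.3 and 125, and the invariant chain Cd74 at 61.7 and 145. In control, H2-Eb1 (14.4 and 38.6) and H2-DMb2 (0 and 2.39) were the 2 called members. Ciita, the activator of MHC class II genes, is counted among the 9. It was not called, at 0.822 FPKM in WT and 0.986 in STAT3-KO control. With IL-33 it was at 1.09 in WT and 0.579 in STAT3-KO, a difference of -0.41 ± 0.20 against the direction of the other members. B cells and dendritic cells carry MHC class II, and of their markers Cd79b (13.1 and 20.4) and Ccr7 (118 and 319) were also higher in STAT3-KO with IL-33. Other markers of these cells were at 0.352 and 0.295 FPKM (Cd79a), 0.184 and 0.129 (Itgax), 0.224 and 0.975 (Zbtb46) and 5.88 and 4.1 (Xcr1).

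Of 11 tested TNF family ligands, 6 were higher and 2 lower in STAT3-KO with IL-33. Tnfsf4, the ligand of OX40, was at 48.8 FPKM in WT and 793 in STAT3-KO, Cd70 at 8.61 and 121, and Lta at 115 and 571. In control, Tnfsf4 (51 and 112), Cd70 (0.146 and 2.46) and Tnfsf8 were higher in STAT3-KO. Of 17 interferon-inducible GTPases, which act against pathogens in vacuoles, 1 rose and 14 fell with IL-33 in WT, such as Ifi47 (from 315 to 91.6 FPKM). In STAT3-KO 8 rose and 7 fell, Igtp rising from 107 to 244 FPKM and Ifi47 falling from 185 to 146 FPKM. The interaction test called 13 with a higher and 0 with a lower response in STAT3-KO. In control, 4 were lower in STAT3-KO and 0 higher, and with IL-33 13 were higher and 0 lower. Of 8 granzymes, cytotoxic proteases, 2 were higher in STAT3-KO control cells (Gzmd and Gzme) and 0 lower. With IL-33 in STAT3-KO 1 rose and 7 fell, among them Gzme (from 13.4 to 0 FPKM), and in WT 1 rose and 4 fell. Of the 4 tested NK cell and ILC1 markers, which share Gzma with the granzymes, Tbx21 was called higher in STAT3-KO control cells and the other 3 were not called. These markers fell with IL-33 in STAT3-KO in 4 of 4 cases (adjusted p = 0.00381, adjusted p = 0.13 with an estimated correlation). The calls in control are among the 55 genes that differed by genotype there, a count that fell to 1 without STAT3-KO control library 1 or 2 and to 0 with the control libraries fitted alone. Several members, such as Tnfsf8, Gbp2 and Gzma, are also in the fixed lists. Gzmd, Gzme, Tgtp1, Tgtp2 and the Gbp genes have near-identical relatives from which the table cannot separate their reads.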
